A study of Homo sapiens with 6 samples.

How the data were processed

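Gene expression was measured in 6 xenograft tumors of CRL-5889, an established line of human squamous lung cancer cells, grown in nude mice and taken at 4 weeks. The implanted cells carried either the fusion TRA2B-DNAH5 (3 tumors) or the vector (3 tumors). Per the labels, RNA was extracted from each tumor with Trizol, labelled with biotin and hybridised to 1 Affymetrix array per tumor. The labels call each tumor a biological replicate and do not say which mouse carried it. Groups and replicate numbers were taken from the sample titles.

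The authors deposited log2 probe set values in a single table with 1 column per array. The log2 scale was read from the values, since the deposited table states no unit, and the background correction, normalization and summarisation behind it are not given in the sources used here. The 6 arrays had nearly the same distribution, with medians from 6.27 to 6.39. No detection call was used, so the precision of each value is limited by the number of arrays and, for dim probe sets, by a background level that is not known.

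Of 49293 probe sets, 44988 named 1 gene, 1832 named several and 2473 were unnamed here. Names came from the platform annotation, and 44961 of the probe sets naming 1 gene had their gene identifier in the RefSeq gene table of GRCh38.p14, with 0 symbols needing an update. That table also gave the order of genes along chromosomes. Its start positions were used only for this order, because no genome build is named for the arrays. For each of 18132 genes, the probe set with the highest mean over the 6 arrays was used. More than 1 probe set was present for 11734 of them. Genes whose probe set had a mean below the 30th percentile of all probe sets (log2 level 4.94) were left out, which removed 4438 genes and left 13694. Control probe sets were not analysed here, so the planned look at spiked and 3' to 5' controls was not run. The planned floors for a linear table did not apply to log2 values.

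Fusion and vector tumors were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no trend, not robust), with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p 0.05. The replicate number was not a term of the model. Error bars on group means are SDs over 3 tumors, and log2 fold changes are given as fusion minus vector with limma's SE. An exact two-sided permutation test over 3 against 3 tumors cannot give a p below 0.1 and is quoted where single genes were tested. Gene lists (27 lists, 535 entries, 499 with a probe set of their own, 426 tested) were compared with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it, each adjusted over the 27 lists. The named genes were TRA2B, DNAH5, SIRT6, MMP1, ACTB and GAPDH, then up to 10 genes per direction with the largest change among those past the threshold with all fusion values on one side of all vector values. Where fewer than 5 passed in a direction, the 5 with the smallest p were named. Up to 4 members with the smallest p were named from each list. SIRT6 and MMP1 were named beforehand as genes that the study is known to concern. That was known when the lists were fixed, and the metalloproteinase list holds MMP1. The groups, tests, lists, naming rule and all alternative settings were fixed before the data were examined.

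The model was tested on simulated data with 13694 genes, 20 runs and 200 genes changed per run, drawn with the spread seen between the tumors and with genes independent of each other. It recovered 51.3% of 1.5-fold, 86.2% of 2-fold, 98% of 4-fold and 99.9% of 8-fold changes, and 4.28% of its calls were false. These shares hold for 200 changed genes per run, which gave 3504 calls over the 20 runs. With fewer changed genes the adjustment is stricter, so recovery in the tumors, where 10 genes passed, can be lower. There the largest unadjusted limma p past the threshold was 2.02e-05. A simulated list shifted 1.25-fold was called in 100% of 20 runs, while 5.19% of lists with no shift had an unadjusted p below 0.05. Here too genes were independent, so both shares can be too favourable for real lists, whose members can vary together. Alternatives covered the filter (none, or the 50th percentile), the choice of probe set, quantile normalization, median centring, a variance trend with robust fitting, array weights, the replicate number as a block, other thresholds and leaving out each tumor in turn. Input was read with the R package data.table, version 1.17.8, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.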

Results

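Transcript levels were compared between 3 tumors of CRL-5889 cells, a human lung squamous carcinoma line, carrying the TRA2B-DNAH5 fusion and 3 tumors of the same line carrying the vector, all grown in nude mice and harvested at 4 weeks. The comparison asks which transcripts differ in established tumors when the cells carry the fusion. The number of arrays, 3 per group, limits the precision. The limma p values measure spread between tumors, and differences between the transfected cell populations cannot be separated from the fusion. Median log2 levels were 6.34, 6.38 and 6.39 in fusion tumors 1 to 3 and 6.27, 6.37 and 6.37 in vector tumors 1 to 3, and the groups did not differ detectably (exact permutation p = 0.5, where 0.1 is the smallest possible). Pearson's r across all probe sets between any 2 arrays lay between 0.989 and 0.997. Vector tumor 1 stood apart from the other 5 on the first principal component, which held 45.1% of the variance (score 30.1, against -8.58 to -3.68 in the others).

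Collagen and matrix degrading enzymes were among the genes that rose most in fusion tumors. MMP1, the interstitial collagenase, rose 4.09-fold, from a log2 level of 8.74 ± 0.44 in vector tumors to 10.77 ± 0.23 in fusion tumors (SD, n = 3 each; log2 fold change 2.03, SE 0.22, adjusted p = 0.0241 by limma with Benjamini-Hochberg adjustment). MMP10, the stromelysin encoded next to MMP1, rose 4.55-fold from 4.88 ± 0.31 to 7.07 ± 0.19 (log2 fold change 2.18, SE 0.17, adjusted p = 0.00629). KRTAP2-3, a keratin-associated protein gene, had the largest rise, 7.60-fold from 6.31 ± 0.37 to 9.24 ± 0.40 (log2 fold change 2.93, SE 0.23, adjusted p = 0.00629). Its probe set is of a type shared by related transcripts and near-identical KRTAP2 genes exist, so the gene assignment is uncertain. The mean of MMP10 in vector tumors lay below the log2 level of 4.94 used as filter on dim probe sets, and a dim level can understate a fold. Both MMP1 probe sets rose alike, with log2 fold changes of 2.03 and 2.18.

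Besides these, 5 genes rose. DAW1, a factor for the assembly of ciliary dynein arms, rose 2.31-fold to 6.31 ± 0.096 from 5.10 ± 0.22, and GLIPR1, a gene induced by p53, rose 2.25-fold to 8.79 ± 0.23 from 7.62 ± 0.15 (SD, n = 3 each). Their adjusted p values were 0.0241 and 0.0277 by limma. FAM241A rose 2.15-fold (log2 fold change 1.10, SE 0.13), ARL14, a small GTPase of the ARF-like family, 1.93-fold (0.95, SE 0.11) and SAMD9, an interferon-inducible antiviral factor, 1.77-fold (0.82, SE 0.087). The vector means of ARL14 (4.71) and SAMD9 (4.68) were below the filter level of 4.94, so their folds too can be understated. Only ZNF22 and PARP8 fell at the threshold of adjusted p 0.05. ZNF22, a zinc finger protein gene, dropped by 1.21 on the log2 scale (SE 0.13, adjusted p = 0.0241), to 5.27 ± 0.16 from 6.48 ± 0.20, and PARP8, an ADP-ribosyltransferase gene, dropped by 0.75 (SE 0.085, adjusted p = 0.0277), to 6.72 ± 0.027 from 7.47 ± 0.060. The next genes by p in this direction, BTBD6 (log2 fold change -1.09, adjusted p = 0.0708), MANSC1 (-0.78, adjusted p = 0.112) and PNMA8A (-1.13, adjusted p = 0.112), did not pass.

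**Figure D1:**
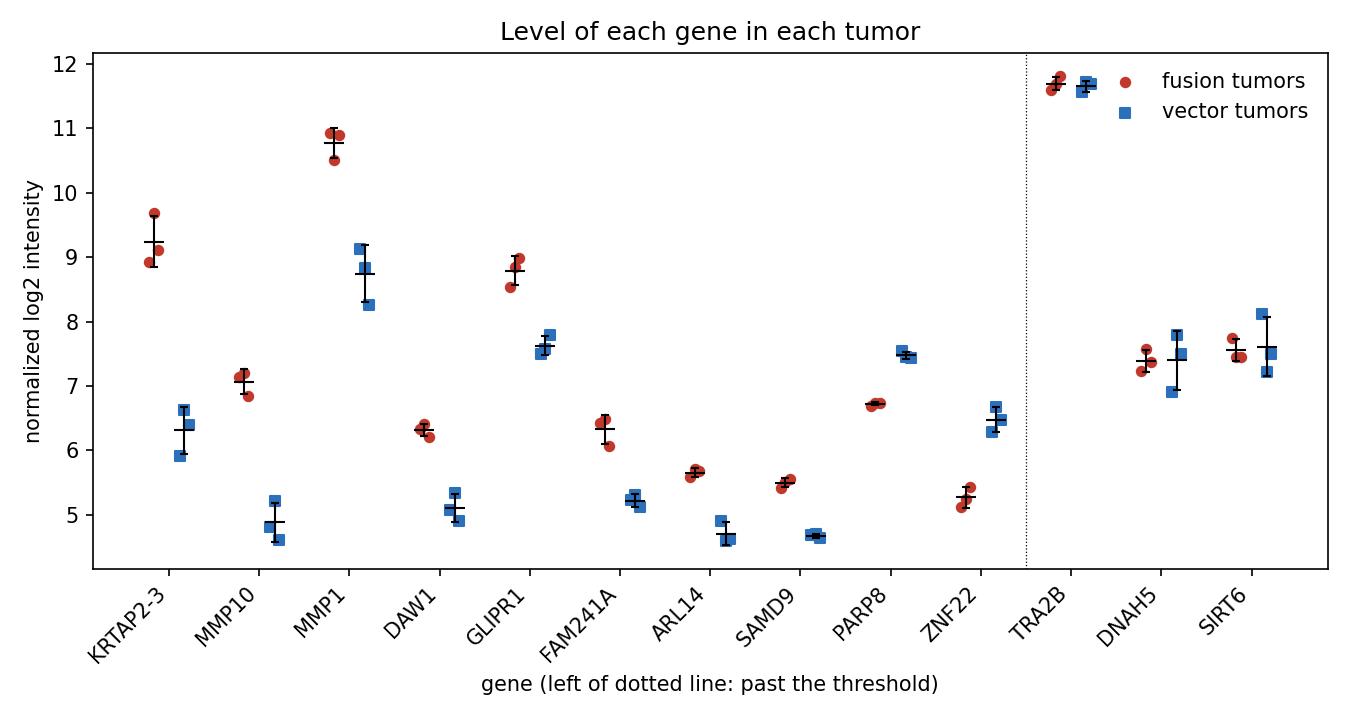
Normalized log2 level of each gene in each of the 3 fusion tumors (circles) and 3 vector tumors (squares), with the mean and SD as bars. The 10 genes left of the dotted line have fusion and vector tumors apart, while TRA2B, DNAH5 and SIRT6 on the right overlap.

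In all, 10 of 13694 genes passed the threshold, 8 higher and 2 lower in fusion tumors, led in size by KRTAP2-3, MMP10 and MMP1. All 10 had every fusion tumor on one side of every vector tumor. Over all tested genes this held for 1600 (11.7%), where chance gives 10%, and 807 genes had an unadjusted p below 0.05, where chance gives 684.7. The count depended on single tumors: limma called 0 genes without fusion tumor 1 (669 at unadjusted p below 0.05), 3 without fusion tumor 2, 3 without fusion tumor 3, 3 without vector tumor 2 and 3 without vector tumor 3. It called 37, among them all 10, without vector tumor 1. KRTAP2-3 and MMP10 lost their call only without fusion tumor 1 (adjusted p = 0.0740 for both). MMP1 lost it without fusion tumor 1 (adjusted p = 0.158), fusion tumor 2 (0.0895), fusion tumor 3 (0.226) or vector tumor 2 (0.125), while the MMP1 log2 fold change stayed between 1.79 and 2.23. Over all settings its adjusted p ran from 0.000800 to 0.226. GLIPR1, ARL14, SAMD9, ZNF22 and PARP8 kept their call only when vector tumor 1 was the tumor left out. DAW1 also kept it without vector tumor 2, and FAM241A without fusion tumor 3. The highest adjusted p in these runs came without fusion tumor 3 for GLIPR1 (0.226), ARL14 (0.287), SAMD9 (0.226) and PARP8 (0.266), and without fusion tumor 1 for DAW1 (0.158), FAM241A (0.188) and ZNF22 (0.158). With all 6 tumors, calls also ended with the most variable probe set of a gene for FAM241A (0.0548), ARL14 (0.0764), SAMD9 (0.0764) and PARP8 (0.109), with the 50th percentile filter for MMP1 (0.0508), GLIPR1 (0.0545) and PARP8 (0.0508), and with median centring for ARL14 (0.0680). The replicate number as a block also ended the calls of ARL14 (limma adjusted p = 0.123), SAMD9 (0.0868) and PARP8 (0.123). Over all settings the log2 fold change stayed between 1.07 and 1.60 for GLIPR1, 0.97 and 1.23 for FAM241A, 0.89 and 1.05 for ARL14, 0.79 and 0.86 for SAMD9, -1.30 and -0.87 for ZNF22, and -0.78 and -0.72 for PARP8.

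**Figure D2:**
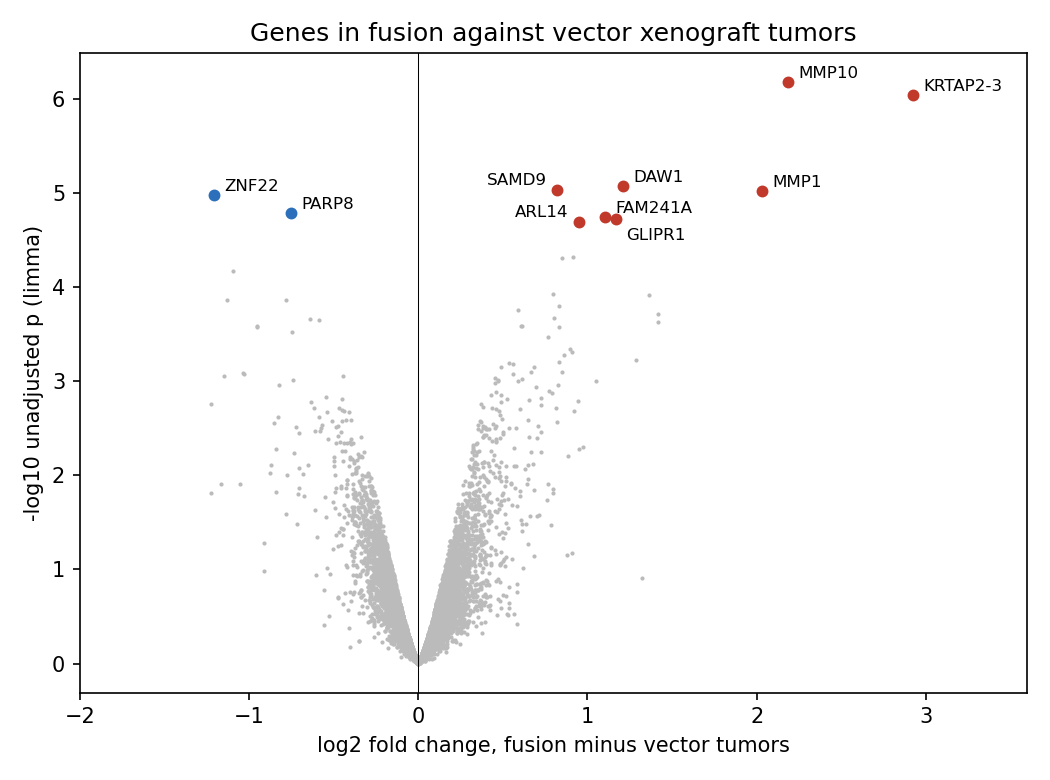
Each point is 1 of 13694 genes, with the log2 fold change (fusion minus vector) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 10 genes past the threshold are named, 8 to the right (higher in fusion tumors) and 2 to the left.

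The genes joined in the fusion did not differ between the groups by this test. TRA2B, a splicing regulator, stood at 11.69 ± 0.11 in fusion and 11.65 ± 0.084 in vector tumors (SD, n = 3 each; 95% confidence interval of the log2 fold change -0.18 to 0.26), and its 10 probe sets gave log2 fold changes of -0.099 to 0.16. DNAH5, an axonemal dynein heavy chain, stood at 7.39 ± 0.17 and 7.40 ± 0.45 (95% confidence interval -0.48 to 0.48), with 2 probe sets at -0.0043 and 0.14. The labels do not say which parts of either gene the construct holds, so these probe sets do not check its presence. SIRT6, a histone deacetylase that the study is known to concern, stood at 7.55 ± 0.17 and 7.61 ± 0.46 (95% confidence interval -0.54 to 0.43), with 5 probe sets from -0.11 to 0.19. Exact permutation p values of the most abundant probe sets were 0.7 for TRA2B, 1 for DNAH5 and 0.8 for SIRT6, against 0.1 for MMP1 and MMP10, the smallest value this design allows. The housekeeping genes ACTB and GAPDH had log2 fold changes of 0.03 (SE 0.096) and 0.06 (SE 0.097).

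Of 27 gene lists, camera called 6, of which 5 were higher and 1 lower in fusion tumors. With an estimated correlation it called 0 (4 at an unadjusted p below 0.05), and fry called 1. The matrix metalloproteinase list (camera adjusted p = 0.0195; adjusted p = 0.333 with an estimated correlation) held MMP1 and MMP10, the 2 of its 14 tested members that rose. The same 2 passed when adjusted over the list alone. Its median log2 fold change was only 0.034, with 8 members above 0 and 6 below, while its mean was 0.36. MMP14, a membrane-bound collagenase, had a log2 fold change of 0.55 (adjusted p = 0.614) and MMP25 one of -0.19, both short of the threshold. MMP3 and MMP12, which lie close to MMP1, were dim and had log2 fold changes of -0.0076 and 0.041, and 5 probe sets of MMP13 gave -0.18 to 0.15. For this list fry, which asks whether the list's genes move one way on balance, gave an adjusted p = 0.00187 and called none of the other 5 lists (adjusted p from 0.205 to 0.437). The metalloproteinase list stayed called whichever tumor was left out, but its call ended with no filter on dim probe sets (adjusted p = 0.200), with the filter at the 50th percentile (0.0569) and with array weights (0.0582), and its range over all settings was 0.000671 to 0.333.

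Transcripts downstream of the ERK kinases leaned higher in fusion tumors. In the ERK pathway output list, 19 of 22 tested members were above 0 (median log2 fold change 0.13, camera adjusted p = 0.0131; adjusted p = 0.333 with an estimated correlation). DUSP5 and DUSP6, phosphatases that are induced by ERK and act on it, had log2 fold changes of 0.82 (SE 0.20, adjusted p = 0.376) and 0.76 (SE 0.24, adjusted p = 0.614), and the growth factor HBEGF and the AP-1 subunit FOSL1 had 0.50 and 0.27. Vector tumors 1 to 3 varied, with DUSP6 at 8.16, 8.86 and 9.22 and HBEGF at 9.41, 8.58 and 7.90. By limma 0 members passed over all genes and 0 when adjusted over the list alone, and 2 had an unadjusted p below 0.05. The list's call ended without fusion tumor 3 (adjusted p = 0.0579) or vector tumor 3 (0.0949) and with the most variable probe set of each gene (0.0845), with a range of 0.000501 to 0.333 over all settings. FOSL1 and EGR1 are also in the list of AP-1 and immediate early genes, which was not called (median 0.024, adjusted p = 0.119). In that list JUN had a log2 fold change of 0.83 (adjusted p = 0.120 over all genes) and was the 1 member past the threshold when adjusted over the list alone. The means of the immediate early list were 8.37, 8.76 and 8.64 in fusion tumors 1 to 3, and 8.83, 8.35 and 8.12 in vector tumors 1 to 3. Without vector tumor 1, which had the highest of these means, the adjusted p was 5.63e-05 for the immediate early list and 0.000501 for the ERK list. Without fusion tumor 1 that of the immediate early list was 0.0205. Without vector tumor 3, which had the lowest of these means, it was 0.998, the highest over all settings.

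Glycolytic and mesenchymal lists were called higher as well. Of 20 glycolysis genes, 15 were above 0 (median 0.11, camera adjusted p = 0.0131; adjusted p = 0.558 with an estimated correlation), among them the enolase ENO2 (log2 fold change 0.40), the hexokinases HK1 (0.26) and HK2 (0.29) and PFKFB3 (0.33), which makes an activator of phosphofructokinase. The mean of the glycolysis list was 9.99 in vector tumor 1, 10.25 and 10.31 in vector tumors 2 and 3 and 10.30 to 10.34 in fusion tumors, and without vector tumor 1 the adjusted p was 0.428. The glycolysis call also ended with the mean of probe sets (0.0694), the most variable probe set (0.0957) and array weights (0.132), with a range of 0.00230 to 0.558 over all settings. Of 17 mesenchymal genes, 14 were above 0 (median 0.086, camera adjusted p = 0.0131; adjusted p = 0.333 with an estimated correlation). They included the transcription factors TWIST2 (0.38) and ZEB1 (0.39), the cadherin CDH11 (0.60) and the collagen cross-linking enzyme LOXL2 (0.29). CDH11 and ZEB1 leaned on 1 tumor each. CDH11 was 6.06 in fusion tumor 1 but 5.08 and 5.23 in fusion tumors 2 and 3. ZEB1 was 8.67 in vector tumor 1 but 9.39 and 9.31 in vector tumors 2 and 3. The mesenchymal call ended without fusion tumor 1 (adjusted p = 0.0567) or vector tumor 3 (0.0870), and with the mean of probe sets (0.427), the most variable probe set (0.670) and array weights (0.0692), with a range of 0.00777 to 0.670 over all settings. In both lists limma called 0 members over all genes and 0 when adjusted over the list alone, with 3 glycolysis and 3 mesenchymal genes at an unadjusted p below 0.05.

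Markers of 2 other cell types were called, in opposite directions. Fibroblast markers were called higher (8 of 12 above 0, median 0.22, camera adjusted p = 0.0299; adjusted p = 0.341 with an estimated correlation), beside the mesenchymal and metalloproteinase lists. None of the 12 passed by limma over all genes, while 4 were up and 1 down at an unadjusted p below 0.05. Adjusted over the list alone, the protease FAP (log2 fold change 0.91), the collagen COL1A1 (0.65) and the surface protein THY1 (0.36) were higher and the microfibril protein FBN1 (-0.50) was lower. Adipocyte markers were called lower (6 of 9 below 0, median -0.14, camera adjusted p = 0.0195; adjusted p = 0.333 with an estimated correlation), with the adipogenic regulator PPARG at -0.38 and the lipid droplet proteins PLIN1 and CIDEC at -0.33 and -0.26. By limma 0 of these 9 passed over all genes or over the list alone, with 3 at an unadjusted p below 0.05. The fibroblast call ended without fusion tumor 1 (adjusted p = 0.0784), fusion tumor 2 (0.0617), vector tumor 1 (0.152) or vector tumor 3 (0.0526), and the adipocyte call without vector tumor 1 (0.0507) or vector tumor 3 (0.189). With the 50th percentile filter, the mean of probe sets, the most variable probe set and array weights, the adjusted p of the fibroblast list was 0.147, 0.259, 0.251 and 0.237 and that of the adipocyte list 0.192, 0.542, 0.561 and 0.132. Over all settings the adjusted p ran from 0.0111 to 0.341 for fibroblast and from 0.00951 to 0.561 for adipocyte markers. The arrays carry human probe sets, and RNA of the mouse host was not told apart from that of the tumor cells, whose own level of these markers is not known. PDGFRA, in the fibroblast list, stood at 13.02 in fusion and 13.16 in vector tumors, near ACTB (13.64 and 13.61). The list therefore cannot be read as fibroblast content alone.

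**Figure D3:**
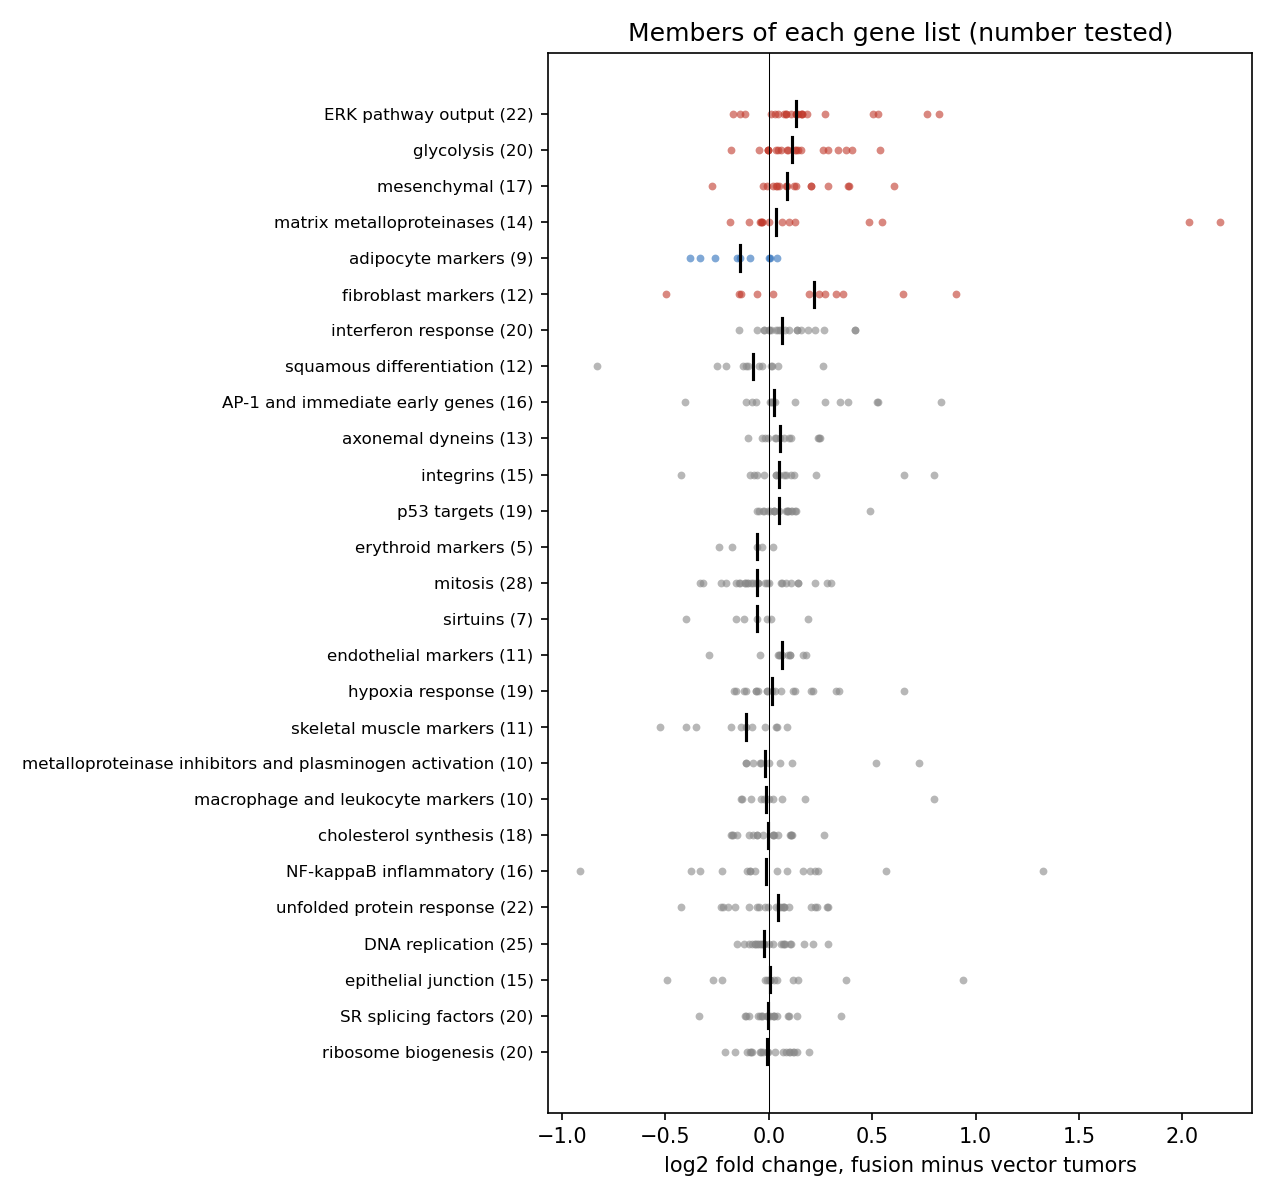
Log2 fold change (fusion minus vector) of every tested member of the 27 gene lists, 1 point per gene, with the number tested in brackets and the median as a vertical bar. Camera called the lists in red as higher and the list in blue as lower, and MMP1 and MMP10 are the 2 points beyond a log2 fold change of 2.

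The other 21 lists were not called with all 6 tumors. Of their 332 tested entries limma called 0 over all genes, with 17 up and 9 down at an unadjusted p below 0.05, and 6 up and 2 down when adjusted over the list alone. Among the latter were the integrins ITGA6 (log2 fold change 0.80) and ITGA4 (0.66), receptors for laminin and fibronectin, although the integrin list as a whole had a median of 0.049 (adjusted p = 0.273) and ITGA2 was at -0.42. CD68, a lysosomal glycoprotein of macrophages, was at 0.80, in a macrophage and leukocyte list with a median of -0.011, a mean of 0.064 with the test following the mean, and an adjusted p = 0.710. SOX2, a transcription factor of squamous lung tumors, was at -0.83 in the squamous differentiation list (median -0.075, adjusted p = 0.0923). The tight junction protein CLDN1 was at 0.94 in the epithelial junction list (median 0.0069, adjusted p = 0.859). There the desmosomal protein DSP was at -0.49 but did not pass over the list alone (limma adjusted p = 0.0601). ANGPTL4 (0.65) stood out in the hypoxia list (median 0.016, adjusted p = 0.349) and SIRT5 (-0.40) in the sirtuin list (median -0.056, adjusted p = 0.297).

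Proliferation, splicing and stress lists lay near 0. Mitosis genes had a median of -0.057 (adjusted p = 0.293), with the proliferation marker MKI67 at 0.28 and the kinesin KIF20A at -0.32. DNA replication genes had a median of -0.024 and a mean of 0.012 (adjusted p = 0.818). Ribosome biogenesis genes had a median of -0.0080 and a mean of 0.0043 (adjusted p = 0.941), and in both lists the test followed the mean. SR splicing factors, the class of TRA2B, had a median of -0.0046 (adjusted p = 0.874), and the axonemal dyneins, the class of DNAH5, one of 0.056 (adjusted p = 0.186). Interferon response genes had a median of 0.064 (adjusted p = 0.0884), with the RNA sensor RIGI at 0.42. The p53 targets had a median of 0.049 (adjusted p = 0.273), the unfolded protein response 0.043 (0.773) and cholesterol synthesis -0.0043 (0.771). The NF-kappaB inflammatory list had a median of -0.013 but a mean of 0.040, with the camera test pointing lower (adjusted p = 0.771) and TNFAIP2 and TNFAIP3 at -0.38 and -0.33. Metalloproteinase inhibitors and plasminogen activation genes had a median of -0.018 but a mean of 0.10, which the test followed (adjusted p = 0.562), with TIMP1 at 0.72 and the urokinase receptor PLAUR at 0.52. Among other cell types, endothelial markers had a median of 0.063 (adjusted p = 0.317), erythroid markers -0.059 (0.278) and skeletal muscle markers -0.11 (0.374). The muscle list mean varied within each group, with 7.13 in fusion tumor 2 and 7.09 in vector tumor 1 against 6.02 to 6.47 in the other tumors. Besides the immediate early list, leaving out 1 tumor brought 4 of the 21 lists past the threshold: interferon response and skeletal muscle without fusion tumor 2 (adjusted p = 0.00222 for both), and squamous differentiation and erythroid markers without vector tumor 2 (0.0111 for both).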

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

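The count of 10 changed genes stayed at 8 to 13 with no filter, quantile normalization, median centring, a variance trend with robust fitting, the replicate number as a block or an adjusted p below 0.10. It was 16 with the mean of all probe sets of a gene, 6 with the most variable probe set, 21 at 2-fold with unadjusted p below 0.05, 2 against a 1.2-fold change (treat), 5 with every probe set tested singly, and 140 with array weights (64.3% higher, against 80%). A filter at the 50th percentile gave 1. It removed 6 of the 10 genes and left MMP1 at an adjusted p of 0.0508 (0.000800 to 0.226 over all settings) with the MMP1 log2 fold change at 2.03. Leaving out each tumor gave 0 (fusion tumor 1; 669 at unadjusted p below 0.05 by limma) to 37 (vector tumor 1) genes, and log2 fold changes of MMP1 from 1.79 to 2.23. The count of called gene lists, 6 in the comparison as reported, was 3 with the 50th percentile filter, 2 with the mean of probe sets and 1 with the most variable probe set, all among the 6. It was 2 with array weights, 1 of them among the 6 and the other the AP-1 and immediate early genes (adjusted p = 0.00101). It was 0 in camera with an estimated correlation (4 at unadjusted p below 0.05), 1 in fry and 2 (vector tumor 3) to 8 (vector tumor 2, with 2 lists not among the 6) when 1 tumor was left out. Apart from the filter and the smaller number of tumors, the cause was not tested. No called value changed direction; values past the threshold in neither setting changed sign in 37 cases for named genes and 36 for lists. No detection level is known, so how far dim genes are limited by background could not be measured. With the replicate block 8 genes were called, 7 of them among the 10, and the same 6 lists. ARL14 (adjusted p = 0.123), SAMD9 (0.0868) and PARP8 (0.123) were not called there, at log2 fold changes of 0.95, 0.82 and -0.75 as without it. Deviations of same-numbered tumors correlated at 0.097, 0.17 and 0.051 across genes. Every tumor correlated best with its own number, a hint from the data only, and the numbers were not taken as a pairing.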

Other observations

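The tests of a regional gain and of fibroblast transcripts for MMP1 and MMP10, those of muscle and short-lived transcripts for vector tumor 1, and the split count and the test without vector tumor 1 for the run of neighbouring genes were chosen after the result was seen.

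Without vector tumor 1, limma called 37 genes at adjusted p below 0.05, 22 higher and 15 lower in fusion tumors, and 32 of them were also among the 140 called with array weights. Those weights counted vector tumor 1 least (0.232, against 0.616 to 2.62 in the others), so this overlap is no separate support. The genes named here were chosen after their values were seen. Besides the 10 genes of the full comparison they included the ERK-induced EGR1 (log2 fold change 1.21 without vector tumor 1, 0.53 with it), DUSP5 (1.03 and 0.82), CLDN1 (1.17 and 0.94), the laminin receptor subunit ITGA6 (0.66 and 0.80) and the receptor tyrosine kinase MET (0.63 and 0.54), all higher in fusion tumors. SOX2 (-1.04 and -0.83), the neuronal microtubule protein gene MAP2 (-1.42 and -1.15) and the guidance factor gene SEMA3E (-1.57 and -1.22) were lower. None of these 8 passed with all 6 tumors.

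A few further genes were picked after their values were seen, outside any list or enrichment test, and none of them passed the threshold with all 6 tumors. The collagen IV chains COL4A1 and COL4A2 had log2 fold changes of -1.17 (SE 0.37, adjusted p = 0.614) and -0.95 (SE 0.16, adjusted p = 0.127), and PXDN, the enzyme that cross-links collagen IV, had -1.03 (SE 0.20, adjusted p = 0.254). NID1, which links laminin to collagen IV, had -0.72 (adjusted p = 0.376) with all 6 tumors and -0.91 without vector tumor 1, where it passed (adjusted p = 0.0440). The laminin chain gene LAMA4 had 1.28 (SE 0.24, adjusted p = 0.236).

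The 6 tumors can be split into 3 against 3 in 10 ways, which is too few for a share under 0.05. The real split gave 10 changed genes, and the highest count in another split was 0 by limma, although those splits had 264 to 1133 genes at an unadjusted p below 0.05. Counting the real split, 1 of 10 gave as many. For gene lists the real split gave 6, the highest other split 8, and 3 of 10 gave as many.

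MMP1 and MMP10 are neighbours and rose by 2.03 and 2.18 on the log2 scale. A gain of the whole region would raise the genes around them by as much, but the upper quartile of 25 tested neighbours that are no metalloproteinases was 0.221 and the highest, CASP4, 0.57, which argues against it. Fibroblast markers rose less than MMP1 and MMP10: the upper quartile of 12 was 0.333, with FAP highest at 0.91 and COL1A1 at 0.65. This cannot decide whether more host fibroblasts contributed, since the probe sets are human and mouse RNA was not told apart. Several markers were also dim, such as POSTN (5.32 in fusion and 5.05 in vector tumors) and COL1A2 (5.46 and 5.22). The region did lean higher, with 23 of 25 neighbours above 0 and a median (0.15) above that of 99.1% of 19613 windows of neighbouring genes, so a small regional shift may add to the rise. The fusion itself stays open as a hypothesis, as do differences between the transfected cell populations that these tumors cannot separate from it.

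Vector tumor 1 lay 0.331 log2 units (root mean square over genes) from its group, while the other 5 lay at most 0.224 from theirs. Muscle in the tissue piece is argued against as the cause because fusion tumor 2 had as high a muscle list mean (7.13, against 7.09 in vector tumor 1; ACTA1 7.84 ± 1.00 in fusion and 8.37 ± 0.68 in vector tumors, SD, n = 3) and lay with the rest, and array scaling because the ratio of the distances was 1.48 as deposited and 1.5 after quantile normalization. Loss of short-lived transcripts could not be decided, since the test used only immediate early genes, whose levels also depend on how strongly they were induced. As a set these genes were not lower in vector tumor 1 than in vector tumors 2 and 3. The lower quartile of their 16 differences was 0.105, and 13 of the 16 were higher (median 0.53). In the same comparison 15 of 16 NF-kappaB inflammatory genes were higher in vector tumor 1 (median 0.26), and 68.9% of 389 genes named ZNF, many of whose transcripts are short-lived, were lower, against 49.9% of all genes (median -0.17). The ZNF genes were picked after they were seen among the lowest in this tumor, so these values test nothing. What set vector tumor 1 apart stays open.

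A run of 31 neighbouring tested genes from VAX1 to ACADSB, centred on SEC23IP and ordered by the GRCh38.p14 gene table, was higher in fusion tumors with a median log2 fold change of 0.340, 30 of 31 genes above 0 and 0 past the threshold by limma (18 had all fusion tumors above all vector tumors). Its median without vector tumor 1 was 0.287. The tumors left had helped to choose the window, so this value cannot decide whether vector tumor 1 alone made the run. The choice of the highest of 12586 windows alone is argued against by windows chosen without 1 fusion and 1 vector tumor. Their median between those 2 tumors was 0.192 to 0.429 in the 9 pairs. Where vector tumor 2 or 3 was left out it was 0.192 to 0.276, which argues against vector tumor 1 alone. That reading of the pairs was chosen after the values were seen. The 10 splits are too few for a share under 0.05 (real value 0.340, highest other 0.203, 1 of 10 as far from 0). A copy number difference between the implanted cell populations may be considered as a hypothesis, with INPP5F (0.65), RAB11FIP2 (0.55) and PLEKHA1 (0.43) among its genes, but DNA was not analysed here. Vector tumor 1 enlarged the first 2 of these values. It was at 8.87 for INPP5F (9.51 and 9.64 in vector tumors 2 and 3) and at 8.35 for RAB11FIP2 (9.15 and 9.05).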
